A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

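RNA of wild-type, C403A and C406A yeast, untreated or treated with 0.03% MMS for 30 minutes, had been hybridized to 12 Affymetrix arrays, 2 for each of the 6 combinations, as the labels give them; the labels number no replicates, and the arrays of a group are called 1 and 2 in the order listed. The values used here are the deposited one-colour signal intensity of each probe set, 9335 per array on a linear scale, per the file headers. The software that summarized probes into these intensity values, and any scaling, is not given in the sources used here. Of the deposited values, 8.95% lay below 0. Array medians ran from 184.5 to 311, a ratio of 1.686. The table held 0 columns of other samples.

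The rule for preparing the data, the comparisons, the gene lists, the genes to be named and most alternatives were written before the data were examined. Under that rule, array medians more than 1.5-fold apart called for quantile normalization, which was computed over the probe sets other than the 60 controls. A floor was set at the 20th percentile of these values (34.463) and log2 was taken. Of the probe sets, 6504 had 1 gene in the name table, 328 had several and 2503 had none, and only the first kind was used, so 2831 were left out. They stood for 5656 genes, 315 of them with several probe sets, of which the brightest was taken. Genes above the floor on fewer than 2 of the 12 arrays were left out (287 genes), and 5369 were tested. A group wholly at the floor gives only a bound, printed as "at least" or "or lower". The arrays of such a group are equal there, so the spread of the gene can be understated and its p too small. Among genes that passed in the wild-type MMS response, 71 had other probe sets and 22 of these had one of opposite sign. A table of the R64 assembly served for names and neighbouring genes only.

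Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, 6 residual degrees of freedom; eBayes with trend, 3.53 prior degrees of freedom), with no blocking term. Contrasts were the MMS response in each strain and their mean, each mutant against wild type without and with MMS, and the differences between MMS responses (interactions). A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Against 27 gene lists limma's camera was run with its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with the rotation test fry. List counts are from the test over all genes and, where stated, from p-values adjusted over the list alone. The size of the response was tested with fry on the interaction contrasts, over the genes that passed in the mean response. Its p was adjusted over the 8 tests of a fit. That choice of genes favours no strain if all groups vary equally. Array weights from limma, lower for more variable arrays, ran from 0.623 for untreated C403A to 1.51 for untreated C406A, so this may not hold.

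Genes named in the text followed a rule: the 8 largest changes each way in an MMS response, where arrays did not overlap between groups, and the 6 largest each way in other comparisons; the 3 of smallest p where fewer than 3 passed; up to 2 members each way of a list described; and 13 genes always, of which 1 had no tested probe set of its own and is not analysed here. THI73 and NSE1, and SSK1 in MMS-treated C406A, were added after their values were seen.

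The scripts were tested on simulated data with 200 changed genes among 5369, in 5 draws. At log2 changes of 0.5, 1 and 2, recovery was 58.5%, 93.4% and 99.1% for the wild-type MMS response (4.78% of calls false), 55.5%, 94.6% and 99.1% for untreated C403A against wild type (3.38% false) and 27.5%, 76.7% and 97% for the C403A interaction (3.6% false). With no change, at most 3 genes passed in any of 20 draws. A list shifted by 0.3 in the wild-type MMS response was the only one of 27 called by camera and by fry. Genes varied independently there, so list calls among genes that vary together were not tested. With a factor of 0.4 on the C403A MMS arrays, the difference between induced and repressed genes was -0.00719 for equal responses and -0.303 for a share of 0.6.

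Alternatives were median scaling, centring, no floor, a floor at the 40th percentile, no filter, no trend, the mean of a gene's probe sets, all probe sets, the compared groups alone, array weights, a 2-fold minimum and leaving out each array. In the setting called no floor, values under 1 were set to 1 so that log2 could be taken. Added after seeing the data were the values as deposited, scaling to 9 hybridization control probe sets, leaving out the 2 arrays of highest ribosomal RNA signal, and 1 wild-type array for each mutant where both share controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.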

Results

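Genome-wide transcript levels of the budding yeast Saccharomyces cerevisiae were measured on 12 one-colour Affymetrix oligonucleotide arrays. The strains were a wild type and a pair of mutants of TFIIH, named C403A and C406A after their amino acid substitutions. TFIIH is the general transcription factor that opens promoter DNA for RNA polymerase II and also unwinds damaged DNA in nucleotide excision repair. The labels do not name the mutated subunit. From knowledge of the study, both substitutions lie in the RING finger of the subunit Ssl1. Each strain was sampled untreated and after 30 minutes in 0.03% methyl methanesulfonate (MMS), a DNA-methylating agent, with 2 arrays in each of the 6 groups. Median deposited intensity per array ran from 184.5 to 311, and the number of arrays limits the precision. Replicate arrays correlated across the 5369 tested genes with r between 0.985 and 0.993, although genes are not independent replicates. Values below are log2 changes of normalized intensity with the standard error of the limma contrast (lmFit, eBayes), and adjusted p is Benjamini-Hochberg adjusted. Nothing in the labels says that arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The arrays were scanned strain by strain, so strain and scan order are confounded.

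The first question was whether the arrays showed the mutated gene itself, SSL1, at different levels. SSL1 intensity in untreated cells was 1720 ± 26.5 (SD, n = 2) in wild type, 4930 ± 128 (SD, n = 2) in C403A and 3590 ± 146 (SD, n = 2) in C406A. This was a log2 rise of 1.52 ± 0.08 in C403A (2.87-fold, adjusted p = 1.92e-05, limma) and of 1.06 ± 0.08 in C406A (2.09-fold, adjusted p = 0.000348, limma). With MMS the rises were 1.58 ± 0.08 (adjusted p = 1.09e-05) and 1.14 ± 0.08 (adjusted p = 0.000281, limma). SSK1, the next annotated gene and the response regulator of the osmosensing phosphorelay, rose with it: by 1.68 ± 0.07 and 1.19 ± 0.07 without MMS, and by 1.54 ± 0.07 and 1.03 ± 0.07 with MMS, in C403A and C406A. LEU2, a leucine synthesis gene often used as a plasmid marker, rose by 0.93 ± 0.06 and 0.77 ± 0.06 without MMS, and by 0.79 ± 0.06 and 0.70 ± 0.06 with MMS. The gene on the other side of SSL1, THI73, did not pass (untreated adjusted p = 0.984 and 0.609), nor did NSE1, the gene beyond SSK1, in untreated cells (adjusted p = 0.911 and 0.492, limma). With MMS, NSE1 rose in C403A (0.35 ± 0.08, adjusted p = 0.0241), a call lost without wild-type MMS array 1 (0.33, adjusted p = 0.109) or 2 (0.37, adjusted p = 0.072) or C403A MMS array 1 (0.32, adjusted p = 0.135) or 2 (0.38, adjusted p = 0.0704). NSE1 did not pass in C406A (0.19 ± 0.08, adjusted p = 0.233, limma), and THI73 passed in neither mutant (adjusted p = 0.762 and 0.639; 0.26 rather than -0.42 in C406A without its MMS array 1). Both neighbours were picked after their values were seen, as was SSK1 in MMS-treated C406A. Their signs are unsettled: THI73 in C403A went from -0.02 to 0.53 without wild-type untreated array 2 and to 0.16 without C403A untreated array 2, in C406A it was -0.04 without wild-type untreated array 1, and NSE1 in C403A became -0.01 and -0.04 without the first and the second of these arrays. MMS did not pass for SSL1 in wild type (-0.03 ± 0.08, adjusted p = 0.813), C403A (0.03 ± 0.08, adjusted p = 0.872) or C406A (0.04 ± 0.08, adjusted p = 0.728, limma). Without wild-type MMS array 2 the wild-type value was 0.03, and without C406A MMS array 1 the C406A value was -0.08.

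**Figure D1:**
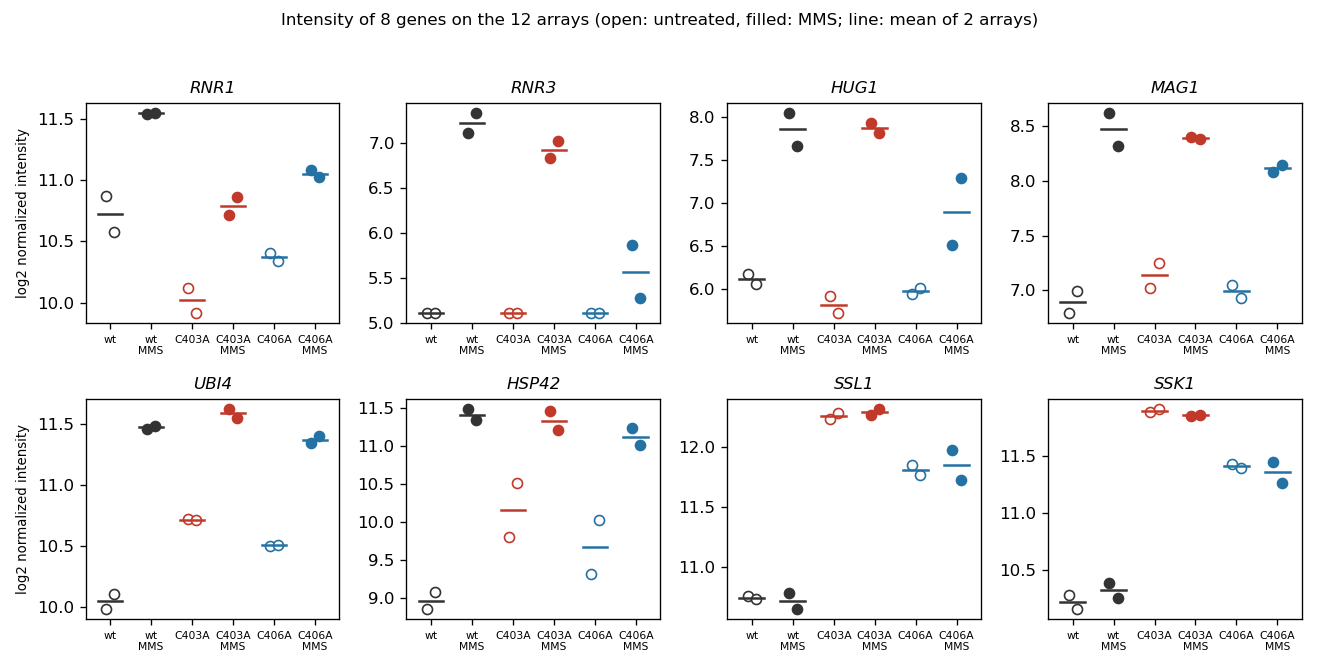
Normalized log2 intensity of 8 genes on each of the 12 arrays, by strain. Open points are untreated arrays, filled points MMS-treated arrays, and lines are the means of the 2 arrays of a group. SSL1 and SSK1 stood higher on every mutant array than on every wild-type array.

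The comparison of treated with untreated wild-type cells asked which transcripts respond to alkylation damage. GRE2, a stress-induced methylglyoxal reductase, rose most, by 4.15 ± 0.49 on the log2 scale (from an intensity of 65.5 ± 48.4 to 1040 ± 13.2, SD, n = 2). One of its 2 untreated arrays lay under the floor, so the rise is inexact: it was 4.91 without wild-type untreated array 1 and 3.38 without array 2, and its adjusted p was at most 0.00333 without any 1 array (limma). The sulfiredoxin gene SRX1 and the sulfite pump gene SSU1 each rose by 2.73 ± 0.10, and the small heat shock protein gene HSP42 by 2.43 ± 0.25. Classical DNA damage genes rose as well: the 3-methyladenine glycosylase gene MAG1 by 1.57 ± 0.13 (adjusted p = 4.65e-05), HUG1 by 1.73 ± 0.23 (adjusted p = 0.000481), and RNR3, the damage-induced large subunit of ribonucleotide reductase, at least 4.32-fold (adjusted p = 6.06e-05, limma) from a level under the floor. The RNR3 call was lost under 1 setting other than leaving out an array (adjusted p = 0.0594, limma). The other ribonucleotide reductase genes RNR1, RNR2 and RNR4 rose by 0.82 ± 0.10, 0.65 ± 0.05 and 0.44 ± 0.05, the polyubiquitin gene UBI4 by 1.43 ± 0.06, and RAD54, DDI1, DIN7 and RPN4 by 1.04, 1.16, 0.94 and 0.41. The RNR4 call was lost in each strain with median scaling (limma adjusted p from 0.0628 to 0.48). With the 40th percentile floor HUG1 rose by 0.64. Falls were led by SFG1, a transcription factor gene of filamentous growth (-2.11 ± 0.30, but -0.87 with the 40th percentile floor, where it no longer led), by the nucleolar protein gene NSR1 (-1.43 ± 0.15) and by HPT1, a purine salvage enzyme (-1.37 ± 0.09).

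By gene list, all 11 measured checkpoint-induced genes rose in wild type (11 adjusted over the list alone; median 0.94, camera adjusted p = 3.72e-08), and so did 33 of 35 proteasome genes (33 adjusted over the list alone; median 0.55), with RPN9 at 0.77 ± 0.14. In the ubiquitin system 15 of 21 rose and none fell (16 rose and 1 fell adjusted over the list alone), and 6 did not pass. Of 28 general stress genes under Msn2 and Msn4, 25 rose (25 adjusted over the list alone; median 1.02), with PGM2 at 2.09 ± 0.18. Oxidative stress genes under Yap1 rose in 17 of 22 cases (20 adjusted over the list alone), the transporter gene ATR1 by 1.91 ± 0.25, and heat shock chaperone genes in 13 of 16 (14 adjusted over the list alone), BTN2 by 1.97 ± 0.16 and HSP82 by 1.02 ± 0.06. Unfolded protein response genes rose in 8 of 12 cases (9 adjusted over the list alone), SIL1 by 0.77 ± 0.08. Sulfur amino acid genes rose in 14 of 22 cases and fell in 1 (15 and 2 adjusted over the list alone), led by MET2 at 1.81 ± 0.10 and STR3 at 1.31 ± 0.09. Against this, 33 of 35 ribosome biogenesis genes fell (35 adjusted over the list alone; median -0.56), NOG1 by -1.23 ± 0.11, and 13 of 14 G2-M genes fell (14 adjusted over the list alone; median -0.63), the mitotic cyclin gene CLB2 by -0.86 ± 0.14. Cytosolic ribosomal protein genes shifted little (median -0.07): 1 of 80 rose and 11 fell (0 and 5 adjusted over the list alone). These 11 lists also passed with an estimated correlation (adjusted p from 0.00621 to 0.0472). Nucleotide excision repair genes rose in 7 of 16 cases and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.01, but adjusted p = 0.0721 with an estimated correlation), RFA1 by 1.16 ± 0.08 and RFA2 by 1.05 ± 0.09. Respiration genes fell in 14 of 41 cases and rose in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.000164, but adjusted p = 0.167 with an estimated correlation; median -0.16, 0.02 as deposited), CYC1 by -0.66 ± 0.08. Other amino acid genes under Gcn4 rose in 18 of 33 cases and fell in 1 (19 and 1 adjusted over the list alone; camera adjusted p = 1.87e-05, but adjusted p = 0.0735 with an estimated correlation), ARG3 by 0.94 ± 0.15.

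In all, 1771 of 5369 genes passed in wild type with limma, 1027 up and 744 down, and 188 of them changed at least 2-fold. The count fell to 1170 without wild-type MMS array 1. Up-regulated genes made up 58% of calls after quantile normalization, 92.1% with the values as deposited and 38.7% with arrays scaled to their hybridization controls. Under those scalings the median of all genes in the MMS responses of wild type, C403A and C406A stood at 0.24, 0.28 and 0.43 as deposited and at -0.09, -0.12 and 0.25 on the hybridization controls, against 0.02, 0.00 and 0.00 after quantile normalization, so list directions are read relative to all genes. As they stood, 23 of the 131 list medians that passed, over all comparisons, changed sign as deposited, 20 on the hybridization controls and 0 with median scaling or centring. Relative to all genes 0 did, which is no test of scaling, since the factor largely cancels there.

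In C403A the same treatment raised GRE2 by 2.95 ± 0.49 (7.73-fold), SRX1 by 2.63 ± 0.10, SSU1 by 2.60 ± 0.10 and the flavohaemoglobin gene YHB1 by 2.13 ± 0.12 (adjusted p = 9.13e-06, limma). At its lowest across the other settings GRE2 rose by 2.204. Checkpoint targets rose: HUG1 by 2.05 ± 0.23 (0.65 with the 40th percentile floor) and RNR3 at least 3.52-fold (adjusted p = 0.00041). For RNR3 the call was lost under 1 setting other than leaving out an array (adjusted p = 0.0725, limma). MAG1 rose by 1.25 ± 0.13, RAD54 by 0.89 ± 0.13, DDI1 by 0.995 ± 0.09, UBI4 by 0.87 ± 0.06, RPN4 by 0.55 ± 0.08, and RNR1, RNR2 and RNR4 by 0.77, 0.38 and 0.34. The RNR2 call was lost with median scaling (0.25, adjusted p = 0.0642), centring (0.25, adjusted p = 0.066), the compared groups alone (adjusted p = 0.0573) and the hybridization controls (0.14, adjusted p = 0.656, limma). DIN7 rose by 0.72 ± 0.13, a call lost without C403A MMS array 2 (0.61, adjusted p = 0.0502). The methionine regulator gene MET28 and MET2 rose by 1.77 ± 0.26 and 1.71 ± 0.10. The largest falls among the genes named were those of COA2, a cytochrome oxidase assembly factor (-1.91 ± 0.30, but -0.83 with the 40th percentile floor), the ergosterol synthesis genes ERG5 (-1.16 ± 0.11) and CYB5 (-1.08 ± 0.10), and the adenine deaminase gene AAH1 (-1.03 ± 0.13).

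In this mutant 11 of 11 checkpoint-induced genes rose (11 adjusted over the list alone; median 0.77), as did 30 of 35 proteasome genes (33 adjusted over the list alone), RPN8 by 0.79 ± 0.06. Yap1 genes rose in 14 of 22 cases (15 adjusted over the list alone), GPX2 by 1.32 ± 0.12, and unfolded protein response genes in 6 of 12 (7 adjusted over the list alone), ERO1 by 1.20 ± 0.22. G2-M genes fell in 10 of 14 cases (12 adjusted over the list alone), ALK1 by -0.75 ± 0.10, and M-G1 genes fell in 8 of 17 and rose in 1 (11 and 1 adjusted over the list alone), ASH1 by -0.59 ± 0.07. Ribosome biogenesis genes fell in 14 of 35 cases (20 adjusted over the list alone; median -0.25, 0.01 as deposited), NOG1 by -0.67 ± 0.11. These lists passed camera with an estimated correlation too (adjusted p from 0.00236 to 0.0396). General stress genes rose in 16 of 28 cases (17 adjusted over the list alone; median 0.55, camera adjusted p = 3.62e-08, but adjusted p = 0.0978 with an estimated correlation). The stress gene DDR2 rose by 1.16 ± 0.21, a call lost without C403A MMS array 1 (1.07, adjusted p = 0.0553). Respiration genes fell in 15 of 41 cases (15 adjusted over the list alone; camera adjusted p = 1.7e-07, but adjusted p = 0.0978 with an estimated correlation; median -0.15, 0.05 as deposited), the cytochrome gene CYT1 by -0.74 ± 0.06. With limma 835 genes passed, 452 up and 383 down, 53 of them at least 2-fold. Leaving out an array took the count to 326 without C403A MMS array 1, 479 without C403A MMS array 2 and 512 without C403A untreated array 1. Up-regulated genes were 54.1% of calls, against 97.8% as deposited and 35.8% on the hybridization controls.

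In C406A MMS raised GRE2 by 3.76 ± 0.49 (13.5-fold), SSU1 by 2.85 ± 0.10, SRX1 by 2.35 ± 0.10 and PLM2, a transcription factor of the damage response, at least 4.43-fold (adjusted p = 0.000273), a call lost with the 40th percentile floor (0.04, adjusted p = 0.608, limma). At its lowest across the other settings GRE2 rose by 2.265. The ribosome-associated stress gene TMA10 rose by 2.15 ± 0.21, PGM2 by 1.92 ± 0.18 and YHB1 by 1.88 ± 0.12. MAG1 rose by 1.12 ± 0.13, DIN7 by 0.96 ± 0.13, DDI1 by 0.86 ± 0.09, UBI4 by 0.87 ± 0.06, RPN4 by 0.55 ± 0.08, and RNR1, RNR2 and RNR4 by 0.68, 0.48 and 0.27. RNR3 did not pass (at least 1.38-fold up, adjusted p = 0.112, limma), except without C406A MMS array 2 (0.75, adjusted p = 0.0218). HUG1 rose by 0.92 ± 0.23 (adjusted p = 0.0187), a call lost without C406A untreated array 1 (0.88, adjusted p = 0.0868), untreated array 2 (0.95, adjusted p = 0.0736) or MMS array 2 (0.53, adjusted p = 0.101), or with the 40th percentile floor (0.04, adjusted p = 0.841). RAD54 rose by 0.53 ± 0.13, a call lost without C406A untreated array 1 (0.46, adjusted p = 0.1) or MMS array 1 (0.46, adjusted p = 0.0846). COA2 (-2.34 ± 0.30), the ribosomal RNA processing gene GRC3 (-2.29 ± 0.22), SFG1 (-2.28 ± 0.30) and AAH1 (-1.58 ± 0.13) fell most among the genes named. With the 40th percentile floor COA2, GRC3 and SFG1 fell by only -1.03, -0.51 and -0.89, less than AAH1.

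The C406A response included 9 of 11 checkpoint-induced genes (10 adjusted over the list alone; median 0.59), 30 of 35 proteasome genes (31 adjusted over the list alone), RPT4 rising by 0.69 ± 0.13, and 24 of 28 general stress genes (24 adjusted over the list alone; median 0.92). Heat shock chaperone genes rose in 9 of 16 cases (11 adjusted over the list alone), BTN2 by 1.47 ± 0.16, and sulfur amino acid genes in 15 of 22 (17 adjusted over the list alone), MET28 by 1.81 ± 0.26. Ribosome biogenesis genes fell in 30 of 35 cases (34 adjusted over the list alone; median -0.54), NOG1 by -1.33 ± 0.11, and G2-M genes in 7 of 14 (11 adjusted over the list alone; median -0.35, 0.13 as deposited). With an estimated correlation these lists passed camera as well (adjusted p from 0.00628 to 0.0312). Gcn4 genes rose in 20 of 33 cases (20 adjusted over the list alone; camera adjusted p = 2.78e-06, but adjusted p = 0.0612 with an estimated correlation), ARG3 by 0.96 ± 0.15. Respiration genes did not pass as a list (camera adjusted p = 0.157), with 5 of 41 falling (4 adjusted over the list alone), HAP4 by -0.53 ± 0.09. The difference of that list from its wild-type response was 0.12 (camera adjusted p = 4.55e-05, but adjusted p = 0.181 with an estimated correlation). With limma 1288 genes passed, 684 up and 604 down, 104 of them at least 2-fold. The count was 678 without C406A untreated array 2, 682 without untreated array 1 and 790 without MMS array 2. Up-regulated genes were 53.1% of calls, against 98.6% as deposited and 93.6% on the hybridization controls.

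**Figure D2:**
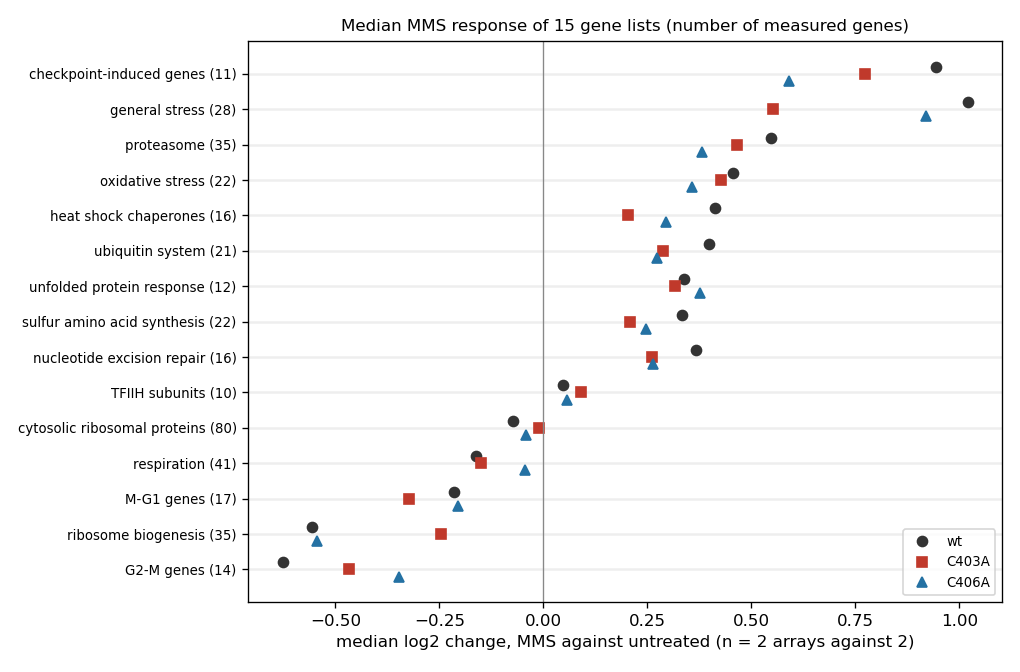
Median log2 MMS response of 15 gene lists fixed beforehand, in wild type, C403A and C406A, each point being the median over the measured members. General stress genes stood at 1.02, 0.55 and 0.92 and ribosome biogenesis genes at -0.56, -0.25 and -0.54 in wild type, C403A and C406A. With values as deposited, whose all-gene medians lie above 0, ribosome biogenesis in C403A (0.01), respiration in wild type and C403A (0.02 and 0.05), G2-M genes in C406A (0.13) and some other medians were above 0, and on the hybridization controls heat shock chaperones in C403A lay below it (-0.02).

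Averaged over the 3 strains, MMS changed 2549 genes with limma, 1357 up and 1192 down, 81 of them at least 2-fold. GRE2 rose by 3.62 ± 0.28, SSU1 by 2.73 ± 0.06, SRX1 by 2.57 ± 0.06, MAG1 by 1.31 ± 0.08 and UBI4 by 1.06 ± 0.03. COA2 fell by 1.87 ± 0.17 (0.76 with the 40th percentile floor), NOG1 by 1.08 ± 0.06 and FAR1, the inhibitor that arrests the cycle in mating cells, by 0.60 ± 0.06. All 35 ribosome biogenesis genes fell (35 adjusted over the list alone), 34 of 35 proteasome genes rose (34 adjusted over the list alone), and all 14 G2-M genes fell (14 adjusted over the list alone), each list passing camera with an estimated correlation (adjusted p from 0.00506 to 0.0172). Of the calls, 53.2% were up, against 96.5% as deposited. Between strains, 380 genes were called up in both wild type and C403A (86.5 for independent lists) and 261 down (53.1). Wild type and C406A shared 572 up (131 for independent lists) and 451 down (83.7), and the mutants shared 327 up (57.6) and 243 down (43.1). In all 3 strains 312 genes rose and 211 fell.

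To ask whether the mutants responded less, the size of the response was compared over the 1357 induced and 1192 repressed genes of the averaged response. The median rise was 0.45 in wild type (1.36-fold), 0.28 in C403A (1.21-fold, 62.1% of wild type) and 0.35 in C406A (1.28-fold, 78.2% of wild type). Per gene, the median difference from wild type was -0.16 in C403A (adjusted p = 0.00728, limma's rotation test fry) and -0.11 in C406A (adjusted p = 0.025, fry). For repressed genes it was 0.09 in C403A (adjusted p = 0.00837) and 0.04 in C406A, which did not pass (adjusted p = 0.121, fry). Between the mutants, the induced genes did not differ past the threshold (-0.06, adjusted p = 0.0695) and the repressed genes did (0.06, adjusted p = 0.0299, fry). The C406A difference over induced genes lost its call without any 1 of its own arrays: untreated array 1 (-0.10, adjusted p = 0.0657) or 2 (-0.11, adjusted p = 0.0532), MMS array 1 (-0.12, adjusted p = 0.0795) or 2 (-0.09, adjusted p = 0.0604, fry). It also missed the threshold with median scaling (adjusted p = 0.0574) and centring (adjusted p = 0.0579, fry), as did the C403A difference over repressed genes (adjusted p = 0.176 and 0.206). As deposited and on the hybridization controls no difference from wild type passed: over induced genes it was -0.04 and -0.23 in C403A (adjusted p = 0.884 and 0.391) and 0.15 and 0.24 in C406A (adjusted p = 0.884 and 0.413), and over repressed genes in C403A 0.26 and 0.10 (adjusted p = 0.883 and 0.528, fry). The positive sign in C406A came with medians of all genes at 0.19 and 0.34, relative to which the induced genes lay at -0.05 and -0.11. The C406A repressed genes passed without wild-type MMS array 2 (0.07, adjusted p = 0.0157, fry). These tests ask whether the genes move one way and do not compare them with other genes. The same sets, examined after this result was seen, already differed before treatment: untreated C403A stood 0.16 above wild type over induced genes, with 77.9% of them higher (adjusted p = 0.00134, fry), and -0.11 over repressed genes (adjusted p = 0.00175, fry). Untreated C406A differed by 0.06 and -0.06 (adjusted p = 0.038 and 0.038, fry). With MMS neither set passed in either mutant (adjusted p from 0.366 to 0.926, fry). One of the untreated C403A arrays, array 2, had ribosomal RNA signals of 1113 for 18S and 2437 for 25S, against at most 691.3 and 610.3 elsewhere, and without it the C403A difference was -0.13 over induced genes (adjusted p = 0.0239) and 0.05 over repressed genes, which no longer passed (adjusted p = 0.0707, fry).

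Gene by gene, the response of C403A differed from that of wild type for 53 genes (limma interaction), 17 higher and 36 lower, 14 of them at least 2-fold. RTC2, a vacuolar amino acid transporter gene, differed from the wild-type response by -2.59 or lower (adjusted p = 0.00117), and with the 40th percentile floor by -0.48, which did not pass (adjusted p = 0.177, limma): it rose at least 6.61-fold in wild type, from under the floor, but was already above it in untreated C403A. The alcohol dehydrogenase gene ADH5 differed by -1.43 ± 0.14 (adjusted p = 0.00428, limma). UBI4 differed by -0.55 ± 0.08 (adjusted p = 0.0218), a call lost without wild-type untreated array 1 (-0.49, adjusted p = 0.0526), wild-type MMS array 1 (-0.56, adjusted p = 0.091) or C403A MMS array 2 (-0.52, adjusted p = 0.063). General stress genes had a smaller response as a list (median -0.69, camera adjusted p = 4.1e-16, but adjusted p = 0.0842 with an estimated correlation), with 5 of 28 lower and none higher (23 adjusted over the list alone). Ribosome biogenesis genes fell less (median 0.25, camera adjusted p = 5.69e-13, but adjusted p = 0.0842 with an estimated correlation), with 1 of 35 passing (5 adjusted over the list alone). The count of 53 became 9 and 20 without wild-type untreated arrays 1 and 2, 2 without wild-type MMS array 1, 91 and 30 without C403A untreated arrays 1 and 2, 18 and 19 without C403A MMS arrays 1 and 2, and 31 without either C406A untreated array. Of the calls 32.1% were higher, against 0% of 2 calls as deposited and on the hybridization controls.

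No gene passed for the response of C406A against that of wild type (0 genes with limma, 451 at unadjusted p under 0.05, where 268.45 would be expected). Other limma settings gave 6 genes with no filter on low genes, 1 without the trend, 3 as deposited, 3 on the hybridization controls and 1 with the compared groups alone. UBI4 had a difference of -0.56 ± 0.08 (adjusted p = 0.0909, limma). For RNR3 both untreated groups lay at the floor, so its value of -1.65 (adjusted p = 0.0921) only repeats the difference between MMS-treated cells; with no floor it was -0.98 (adjusted p = 0.926, limma). Both passed without C406A MMS array 1 (UBI4 -0.53, adjusted p = 0.0384, and RNR3 -1.95, adjusted p = 0.00369, under the same limit), where 54 genes passed in all. The count was also 20 without wild-type MMS array 2 and 1 without wild-type untreated array 1 or either C403A MMS array. For checkpoint-induced genes the list difference was -0.16 (0.07 as deposited and 0.22 on the hybridization controls; camera adjusted p = 0.00192, but adjusted p = 0.0744 with an estimated correlation), with 0 of 11 passing by limma (1 lower adjusted over the list alone). By its median it did not stand out. Camera called 7 lists lower, the other 6 with medians from -0.20 (general stress) to -0.10 (ubiquitin system). All 7 medians were above 0 as deposited and on the hybridization controls, but below the medians of all genes there, 0.19 and 0.342. Under those scalings camera with its preset correlation still called the checkpoint list lower (adjusted p = 0.000547 and 0.000383). The general stress and the alkylation and base excision repair lists kept their calls too, and the rest of the 7 lost theirs. After quantile normalization camera called 5 lists higher. No list was called with an estimated correlation. The average of both mutants differed from wild type for 10 genes, 3 higher and 7 lower, and the mutants differed from each other for 6, 2 higher and 4 lower in C403A. Those counts ranged from 0 to 48 and from 0 to 64 as single arrays were left out, both highest without C406A MMS array 1. The mean count was 0 without wild-type MMS array 1, C403A MMS array 2 or C406A untreated array 2, and the count between mutants was 0 without any 1 of the wild-type arrays or either C406A untreated array.

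The untreated C403A strain was compared with untreated wild type to ask how it differs without damage. SSL1, SSK1 and LEU2 were also higher in both mutants. Differences of either mutant from wild type therefore cannot be credited to the substitution alone. Apart from SSL1, SSK1 and LEU2, the largest named rise was RTC2, at least 4.91-fold (adjusted p = 3.75e-05), a call lost with the 40th percentile floor (0.19, adjusted p = 0.299, limma). Mating genes were lower: FIG1, a membrane protein of mating cells, by -1.93 ± 0.18, the agglutinin anchor gene AGA1 by -1.21 ± 0.11 and PRM6 at least 3.15-fold. The iron transporter gene FET4 (-1.48 ± 0.11), the arginine synthesis gene ARG3 (-1.41 ± 0.15) and RNR1 (-0.71 ± 0.10, adjusted p = 0.00258) fell, while SRX1 (0.998 ± 0.10) and UBI4 (0.67 ± 0.06, adjusted p = 0.000245) rose. The other 9 of the 12 always-named genes did not pass (adjusted p from 0.258 to 1). Respiration genes rose in 28 of 41 cases (32 adjusted over the list alone; median 0.36, camera adjusted p = 5.49e-15, but adjusted p = 0.0828 with an estimated correlation), COX13 by 0.92 ± 0.12 and ATP7 by 0.71 ± 0.12. Haploid and pheromone response genes fell in 7 of 11 (7 adjusted over the list alone; median -0.65, camera adjusted p = 1.16e-06, but adjusted p = 0.0556 with an estimated correlation). M-G1 genes fell in 7 of 17 and rose in 1 (9 and 1 adjusted over the list alone; median -0.50, adjusted p = 0.0496 with an estimated correlation), the daughter-cell wall genes DSE2 and DSE1 by -0.94 ± 0.10 and -0.87 ± 0.10. General stress genes rose in 10 of 28 (11 adjusted over the list alone; camera adjusted p = 0.000254, but adjusted p = 0.263 with an estimated correlation), and ribosome biogenesis genes fell in 9 of 35 (13 adjusted over the list alone; camera adjusted p = 8.02e-07, but adjusted p = 0.164 with an estimated correlation), NSR1 by -0.94 ± 0.15. G2-M genes rose in 6 of 14 (6 adjusted over the list alone; camera adjusted p = 0.00741, but adjusted p = 0.164 with an estimated correlation, and camera adjusted p = 0.0817 without C403A untreated array 1), KIN3 by 0.69 ± 0.09. In all 759 genes passed with limma, 492 up and 267 down, 58 of them at least 2-fold. The count was 471 and 364 without wild-type untreated arrays 1 and 2, 402 without C403A untreated array 2, and 199 without both arrays of highest ribosomal RNA signal. Up-regulated genes were 64.8% of calls and 10.3% on the hybridization controls.

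Untreated C406A differed less in number of genes. The pheromone-regulated genes FIG1 (-1.88 ± 0.18, adjusted p = 0.0012), FIG2 (-1.35 ± 0.17) and AGA1 (-0.93 ± 0.11) fell, and so did the chitinase gene CTS1 (-0.49 ± 0.06). RTC2 rose at least 2.52-fold (adjusted p = 0.002, limma, but 0.00 with adjusted p = 1 at the 40th percentile floor) and UBI4 by 0.46 ± 0.06 (adjusted p = 0.00435, but 0.0504 without C406A untreated array 2). RNR1 did not pass (-0.35 ± 0.10, adjusted p = 0.108) except without wild-type untreated array 2 (-0.50, adjusted p = 0.0494), and 10 of the 12 always-named genes did not pass (adjusted p from 0.108 to 1). Respiration genes rose in 15 of 41 cases (30 adjusted over the list alone; median 0.31, camera adjusted p = 1.19e-21, but adjusted p = 0.051 with an estimated correlation). Haploid and pheromone response genes fell in 4 of 11 (7 adjusted over the list alone; camera adjusted p = 4.65e-07, but adjusted p = 0.051 with an estimated correlation), and M-G1 genes fell in 4 of 17 and rose in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.000518, but adjusted p = 0.051 with an estimated correlation). With limma 145 genes passed, 98 up and 47 down, 12 of them at least 2-fold. Single arrays moved this count strongly: it was 67 and 88 without wild-type untreated arrays 1 and 2, 32 and 21 without C406A untreated arrays 1 and 2, and 96 without either C403A MMS array. Of the calls 67.6% were up, against 78.5% with median scaling, 80.2% with centring, 46.7% as deposited and 11.8% on the hybridization controls.

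With MMS, C403A again differed from wild type in ARG3 (-2.07 ± 0.15, 4.19-fold, adjusted p = 7.8e-05), the cell wall gene HPF1 (-1.59 ± 0.08), the lactate dehydrogenase gene CYB2 (-1.51 ± 0.16, but -0.37 with the 40th percentile floor), FET4 (-1.49 ± 0.11) and FIG1 (-1.48 ± 0.18), all lower. Higher in the mutant were the alpha-factor gene MF(ALPHA)2 (1.54 ± 0.10) and COQ21 (1.42 ± 0.14). RNR1 was lower by -0.75 ± 0.10 (adjusted p = 0.00181, limma). The other 2 always-named genes that passed were SSL1 and RNR2 (-0.25 ± 0.05, adjusted p = 0.0133), the latter lost without wild-type MMS array 1 (-0.26, adjusted p = 0.0574), wild-type MMS array 2 (-0.24, adjusted p = 0.0618) or C403A MMS array 2 (-0.22, adjusted p = 0.0789). Respiration genes were higher in 30 of 41 cases (34 adjusted over the list alone; camera adjusted p = 2.71e-14, but adjusted p = 0.0552 with an estimated correlation), the regulator gene HAP4 by 0.70 ± 0.09. G2-M genes were higher in 8 of 14 (9 adjusted over the list alone; camera adjusted p = 9.78e-06, but adjusted p = 0.0552 with an estimated correlation), KIN3 by 0.82 ± 0.09 and CHS2 by 0.72 ± 0.11. M-G1 genes were lower in 7 of 17 and higher in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.0456 with an estimated correlation), DSE2 by -1.24 ± 0.10 and CTS1 by -1.04 ± 0.06. Gcn4 genes were lower in 15 of 33 and higher in 1 (17 and 2 adjusted over the list alone; camera adjusted p = 2.95e-06, but adjusted p = 0.101 with an estimated correlation), ILV5 by -0.78 ± 0.08. Glycolysis genes were lower in 6 of 18 (6 adjusted over the list alone; median -0.09, 0.01 as deposited; camera adjusted p = 0.000148, but adjusted p = 0.0552 with an estimated correlation), the phosphofructokinase gene PFK2 by -0.67 ± 0.05. Checkpoint-induced genes were lower in 2 of 11 (2 adjusted over the list alone; median -0.18, camera adjusted p = 0.0362, but adjusted p = 0.141 with an estimated correlation, and lost without wild-type or C403A MMS array 1, camera adjusted p = 0.0785 and 0.0564). In all 728 genes passed with limma, 401 up and 327 down, 44 of them at least 2-fold. The count was 320 and 443 without wild-type MMS arrays 1 and 2 and 316 and 364 without C403A MMS arrays 1 and 2. Of the calls 55.1% were up, against 4.26% on the hybridization controls.

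With MMS, C406A had lower checkpoint targets than wild type: RNR3 by -1.65 ± 0.19 (3.14-fold lower, intensity 48.4 ± 13.8 against 149 ± 16.6, SD, n = 2; adjusted p = 0.00266, limma) and HUG1 by -0.96 ± 0.23 (adjusted p = 0.0493). In the setting called no floor, where values under 1 were set to 1, the RNR3 difference was -1.65 but did not pass (adjusted p = 0.636, limma). Its spread there draws on the untreated arrays too, where RNR3 lay under the main floor. HUG1 lost its call in 11 of the 12 fits without 1 array: the adjusted p was 0.25 and 0.0739 without wild-type MMS arrays 1 and 2 (-0.77 and -1.15) and 0.129 without C406A MMS array 1 (-0.56), and 0.0559 to 0.0813 without any 1 of the untreated or C403A arrays (-0.96). It passed without C406A MMS array 2 (-1.35, adjusted p = 0.0176). RNR1 (-0.49, adjusted p = 0.0283) and RNR2 (-0.22, adjusted p = 0.046, limma) were lower too, calls lost in 6 and 9 of the 12 fits without 1 array. Apart from these genes and SSL1, the 7 other always-named genes did not pass (adjusted p at least 0.0786, limma). As a list, checkpoint-induced genes were lower in 4 of 11 cases (6 adjusted over the list alone; median -0.22, adjusted p = 0.0352 with an estimated correlation). The median in C403A was near, at -0.18. Between the mutants, the MMS response of that list did not differ past the threshold (0.07, camera adjusted p = 0.477). Respiration genes were higher in 31 of 41 (36 adjusted over the list alone; median 0.46, adjusted p = 0.03 with an estimated correlation) and G2-M genes in 8 of 14 (10 adjusted over the list alone; median 0.42, adjusted p = 0.03 with an estimated correlation), the bud neck gene BUD4 by 0.59 ± 0.07, a call lost with the mean of its probe sets (0.22, adjusted p = 0.374). CTS1 (-0.62 ± 0.06), DSE2 (-0.80 ± 0.10) and PFK2 (-0.51 ± 0.05) were lower and the cell wall gene PIR3 (0.90 ± 0.11) higher. SNR4, a small nucleolar RNA, was lower by -1.62 ± 0.21 (adjusted p = 0.00393). With limma 243 genes passed, 146 up and 97 down, 15 of them at least 2-fold. The count was 74 and 161 without wild-type MMS arrays 1 and 2, 57 without C406A MMS array 2, 159 without either C403A MMS array and 138 without either C406A untreated array. Of the calls 60.1% were up, against 74.3% with median scaling, 75.2% with centring and 76.1% on the hybridization controls.

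Both mutants were compared with the same wild-type arrays, so part of any overlap may come from those shared controls. Untreated, 90 genes were higher and 41 lower in both (8.98 and 2.34 for independent lists, 0 in simulations with no effect). The 0 was all but fixed in advance, since hardly any gene passes where nothing changes. Independent lists ignore the shared arrays. Neither value, here or with MMS, therefore shows how much of the overlap comes from the shared controls. Across genes the changes of the mutants correlated with r = 0.65, where 100 simulations of unchanged groups gave 0.502, and had a covariance of 0.0529 against 0.0136. With MMS 110 were higher and 57 lower in both (10.9 and 5.91 for independent lists, 0 in simulations), with r = 0.496 against 0.499 and a covariance of 0.0406 against 0.0135. In a split chosen after these results, 1 wild-type array served each mutant, and r was 0.458 and 0.265 untreated and 0.311 and 0.216 with MMS, for the 2 ways of assigning the arrays. There 20 simulations of unchanged groups gave -0.012 and 0.00075 untreated and 0.011 and -0.0022 with MMS. Simulated arrays varied independently, so anything common to both wild-type arrays of a treatment is not removed by the split. The covariance was 0.0422 and 0.0283 untreated and 0.0289 and 0.0218 with MMS.

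**Figure D3:**
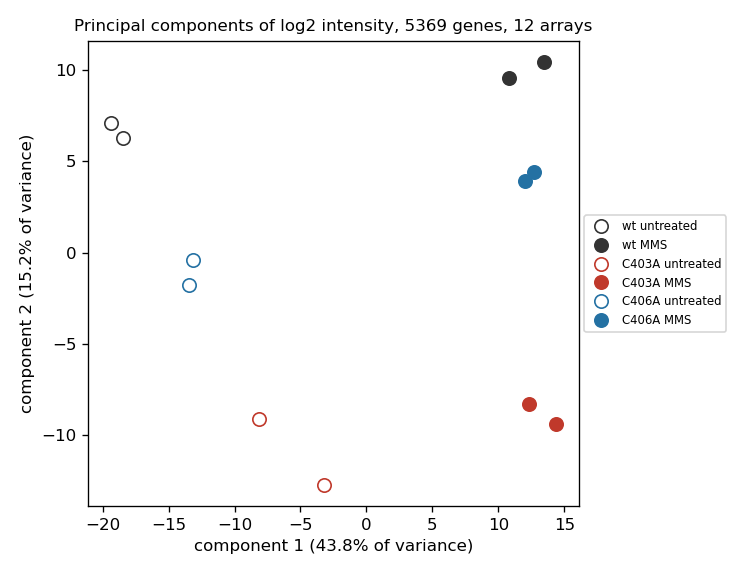
First and second principal components of the 12 arrays, holding 43.8% and 15.2% of the variance over the 5369 tested genes. Untreated arrays lay between -19.4 and -3.25 on the first component, C403A nearest to the MMS arrays, which lay between 10.8 and 14.4.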

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

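Tests of the array with high ribosomal RNA signal and of scaling were chosen after the results were seen, and the test of mixed RNA before. A difference between strains in the MMS response itself (limma interaction, or fry on the interaction for sets of genes) brought the following results here, and the array signals come from control probe sets outside the gene comparisons.

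The MMS response was smaller in C403A: the median difference from wild type was -0.159 over induced and 0.0937 over repressed genes, against -0.108 over induced genes in C406A, -0.129 and 0.0693 for the mean of both mutants, and 0.0586 over repressed genes between C403A and C406A. The untreated C403A array with high ribosomal RNA signal is argued against as the whole cause, since the induced-gene difference was -0.13 without it (adjusted p = 0.0239, fry). A single scaling factor per array moves induced and repressed genes alike and is argued against by the gap between them, -0.338 to -0.18 without each array. But the induced-gene difference alone did not pass as deposited (-0.0439, adjusted p = 0.884) or on the hybridization controls (-0.234, adjusted p = 0.391, fry). Quantile normalization, which adjusts by intensity, gave a gap of -0.252. Without that step the gap was -0.244 with median scaling, -0.243 with centring, -0.306 as deposited and -0.335 on the hybridization controls. Other scaling that varies with intensity was not tested. For repressed genes the array with high ribosomal RNA signal stays open, since the difference shrank to 0.0501 without it. Treated RNA mixed into the untreated C403A samples stays open, as does a higher stress level of those cells. The implied share in the most against the least induced quartile had a ratio of 0.509. Its 95% interval was 0.371 to 0.687 (2000 resamples of genes), which spans the bound of 0.5 set for it. The shares were 36.9% and 72.6%, where mixing alone would give alike shares. Resampling genes leaves out variation between arrays, and quartiles and response each rested on a single pair of C406A arrays.

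Genes whose MMS response differed between strains by limma numbered 53 for C403A against wild type, 10 for the mean of both mutants and 6 between the mutants. In C403A the highest differences were YFR035C at least 1.37, PPT2 0.99, MF(ALPHA)2 0.95, FAL1 0.84, NOP16 0.82 and RFU1 0.77, with adjusted p from 0.017 to 0.0379. The lowest were RTC2 -2.59 or lower, ATG1 -2.22, ECM27 -1.59, YCR099C -1.57, ADH5 -1.43 and YPS6 -1.35, with adjusted p from 0.00117 to 0.0379. RTC2 and ADH5 kept their calls in all 12 fits without 1 array, and the others lost theirs in 2 (NOP16) to 11 (RFU1, ATG1) of them.

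For the mean of both mutants the differences were NOP16 0.58, SAS10 0.54, ALB1 0.52, RTC2 -1.72 or lower, RIM13 -1.16 or lower, ADH5 -0.85, UBI4 -0.56, HSP82 -0.50 and EHT1 -0.45 (adjusted p from 0.0123 to 0.0496, limma), each lost in 3 (RTC2) to 11 (NOP16, ALB1) of the 12 fits without 1 array. Between C403A and C406A they were UTP23 0.85, RBG1 0.45, RTC2 -1.73, ADH5 -1.16, YAP1801 -1.11 and SNZ1 -0.80 (adjusted p from 0.0256 to 0.0296, limma), each lost in 8 of those fits. With the 40th percentile floor RTC2 did not pass in C403A (-0.48, adjusted p = 0.177) or in the mean (-0.01, adjusted p = 0.989, limma).

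Ribosomal RNA signals on untreated C403A array 2 were 1113 (18S) and 2437 (25S). The URA3 control signal was 1010 on untreated C406A array 2 and 1119 on MMS-treated C406A array 1, against 508.1 to 638.8 on the other 10 arrays.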

How the results depend on the processing

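Values as deposited, scaling to hybridization controls, leaving out the 2 arrays of highest ribosomal RNA signal and taking 1 wild-type array for each mutant were tests chosen after the data were seen, and the others before. Of the values of single genes recomputed under settings other than leaving out an array, 2568 kept direction and side of the threshold, 363 lost and 8 gained a call and 11 reversed. List direction was that of camera, against other genes, and not the sign of the median. On that measure 1172 list values kept, 110 lost and 1 reversed. Without 1 array, 2434 gene values kept, 310 lost, 8 gained and 8 reversed, and 1482 list values kept and 90 lost. Where an array left out leaves 1 in its group, that lone sample is assumed to vary like the other groups. No paired analysis was possible because the labels carry no replicate numbers. A batch block was not run, since all arrays came from 1 chip lot and 1 scan day. On that day the arrays were scanned strain by strain: wild type at positions 1 to 4, C403A at 5 to 8 and C406A at 9 to 12. Within each strain untreated arrays came before MMS arrays. Comparisons of a mutant with wild type, and of MMS with untreated cells within 1 strain, therefore cannot be told apart from scan order. Over all strains, untreated and MMS arrays alternated in pairs. On the first principal component MMS arrays at positions 3, 4, 7 and 8 lay between 10.84 and 14.39. Untreated arrays scanned at positions 5, 6, 9 and 10 lay between -13.44 and -3.245. These values argue against a steady drift over the day as the source of the MMS difference common to the strains. Low signal limits genes near the floor: RNR3 had no value at the 40th percentile floor. Unless stated, the cause was not tested.

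Median scaling gave 136 genes for C406A against wild type with MMS (main 243), 1 for the mean interaction (10), and size differences of 0.0879 over repressed genes in C403A (adjusted p = 0.176) and -0.108 over induced genes in C406A (adjusted p = 0.0574, fry). Centring gave 137, 1, 0.0868 (adjusted p = 0.206) and -0.109 (adjusted p = 0.0579, fry), and 33 for the C403A interaction (53). The 40th percentile floor gave 17 for the mean interaction and 18 between the mutants (6), no filter gave 6 for the C406A interaction (0) and 15 between the mutants, and the mean of probe sets gave 14 between the mutants. Without the trend the counts were 140 for C406A with MMS, 1 for the C406A interaction, 3 for the mean and 1 between the mutants. All probe sets gave 32 for the C403A interaction and 1 for the mean. Array weights gave 429 and 228 for untreated C403A and C406A (759 and 145) and 29 for the C403A interaction.

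The compared groups alone, with fewer degrees of freedom, gave 109 for the C403A MMS response (835), 3 and 0 for untreated C403A and C406A, 209 (728) and 0 with MMS, and 1, 1 and 0 for the C403A, C406A and between-mutant interactions. A 2-fold minimum, which can only remove genes, left 188, 53, 104 and 81 in the wild-type, C403A, C406A and mean MMS responses, 58, 12, 44 and 15 for C403A and C406A untreated and with MMS, and 14, 2 and 3 for the C403A, mean and between-mutant interactions. With an estimated correlation camera called 11 lists in the wild-type MMS response (19), 1 and 0 in untreated C403A and C406A (9 and 6), 1 and 3 with MMS (8 and 8) and 0 in each of the 4 interactions. Fry called 24, 23 and 24 lists in the C403A, C406A and mean MMS responses, 19 in untreated C403A and 7 in the C406A interaction.

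As deposited, counts were 793 and 367 for the wild-type and C403A MMS responses, 98 and 15 for untreated C403A and C406A, 79 and 37 with MMS, and 2, 3, 1 and 2 for the C403A, C406A, mean and between-mutant interactions. The induced-gene size difference was -0.0439 in C403A (adjusted p = 0.884) and 0.145 in C406A, a reversal (adjusted p = 0.884) but -0.0457 relative to all genes, which stood at 0.19, and the repressed one in C403A 0.262 (adjusted p = 0.883, fry). On the hybridization controls they were 824, 212 and 1590 for the wild-type, C403A and mean MMS responses, 339 and 76 for the untreated mutants, 46 for C406A with MMS, 2 and 3 for the C403A and C406A interactions and 0 for the mean. Sizes there were -0.234 (adjusted p = 0.391), 0.235, a reversal (adjusted p = 0.413) but -0.107 relative to all genes, which stood at 0.342, and 0.101 (adjusted p = 0.528, fry). Without the 2 arrays of highest ribosomal RNA signal the counts were 199 for untreated C403A, 8 for the C403A interaction and 5 for the mean.

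Genes with reversed values had not passed. SSL1 in the C403A MMS response was -0.13 with median scaling, -0.13 with centring and -0.24 on the hybridization controls, in C406A -0.085 with median scaling and with centring, and in wild type 0.18 as deposited. Without 1 array SSL1 ranged from -0.082 (without C406A MMS array 1) to 0.17 in C406A and from -0.094 to 0.034 (without wild-type MMS array 2) in wild type. THI73 ranged from -0.041 (without wild-type untreated array 1) to 1.05 in untreated C406A and from -0.57 to 0.53 in untreated C403A (0.53 and 0.16 without array 2 of either group), and was 0.71 there without both; in MMS-treated C406A it ranged from -1.09 to 0.26 (without C406A MMS array 1). NSE1 in untreated C403A ranged from -0.040 to 0.077 (-0.013 and -0.040 without array 2 of either group), and was -0.072 without both and -0.24 on the hybridization controls, and in untreated C406A -0.10 as deposited and -0.19 on the controls. The proteasome list in the C406A interaction, which had passed at -0.109 but not with an estimated correlation (adjusted p = 0.0744), was 0.294 on the hybridization controls (adjusted p = 0.997, camera), below the median of all genes there, 0.342.

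Some named genes kept their sign with a much smaller value. The 40th percentile floor gave 0.16 for PLM2, 0.62 for RTC2, -0.87 for SFG1 and 0.64 for HUG1 in the wild-type MMS response. It gave -0.83 for COA2, 0.65 for HUG1 and 0.34 for DIN7 in C403A, and -0.51 for GRC3, -0.89 for SFG1, 0.41 for DIN7 and 0.96 for MET28 in C406A. It gave -0.37 for CYB2 in MMS-treated C403A and -0.79 for ATG1 in the C403A interaction. As deposited, ALK1 (-0.44), ASH1 (-0.30) and NOG1 (-0.37) in the C403A MMS response and HAP4 (-0.09) in C406A did not pass. On the hybridization controls UBI4 in untreated C406A (0.14), and HAP4 (0.40) and NSE1 (0.06) in MMS-treated C403A, did not pass. GRE2 was as low as 2.806, 2.204 and 2.265 in the wild-type, C403A and C406A MMS responses, and 2.425 in their mean, under a setting other than leaving out an array.

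Without 1 array, counts ranged from 1170 to 1878 in the wild-type MMS response, 326 to 799 in C403A, 678 to 1406 in C406A and 2212 to 2571 in the mean. They ranged from 364 to 800 and 21 to 203 for untreated C403A and C406A, 316 to 829 and 57 to 303 with MMS, and 2 to 91, 0 to 54, 0 to 48 and 0 to 64 for the C403A, C406A, mean and between-mutant interactions. Size differences ranged from -0.201 to -0.13 and -0.135 to -0.0898 over induced genes in C403A and C406A, and 0.0501 to 0.141 and 0.0148 to 0.0689 over repressed genes.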

Other observations

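Tests of SSL1 and SSK1, the shares of RNR3 and HUG1 alone, and the comparison of untreated mutants with MMS responses were chosen after the results were seen, and the other tests, with the split of arrays, before.

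SSL1 and its neighbour SSK1 stood higher in both mutants, and LEU2 with them. A joint rise of TFIIH subunit genes is argued against by the other 9 subunits, whose median change over both untreated mutants was 0.0115 (75th percentile 0.22), although TFB3 rose (0.65, limma adjusted p = 0.0202 in C403A and 0.313 in C406A). Array scaling is argued against by the lowest SSL1 change over 5 scalings, 0.855 (highest 1.62). Extra copies of a segment that carries SSL1 and SSK1 stay open, since the rank of SSK1, 4 of 5369 genes by mean change, only restates the pattern. Copy number was not measured, and the rise of NSE1 in MMS-treated C403A is outside this test.

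RNR3 and HUG1 were lower in MMS-treated C406A than in wild type, although the MMS responses did not differ past the threshold (limma interaction, adjusted p = 0.0921 and 0.546). For RNR3, a single array is argued against by differences of -1.94 to -1.36 without each of the 4 arrays, but HUG1 passed in 1 of those 4 fits, with differences from -1.35 to -0.56. Weaker MMS exposure of the C406A cultures remains possible. Checkpoint-induced genes kept 74.9% of the wild-type response, against 73.8% for the median of 10000 matched lists (5th percentile 57.9%, rank of the list at percentile 54.9). HUG1 itself kept 52.9%, at percentile 22 of 50 genes of like response. The share of RNR3 was 21.8%, at percentile 8 of 50 such genes. It divides 1 bound by another, as RNR3 lay under the floor on every untreated array. With no floor, where values under 1 were set to 1, RNR3 rose by 4.73 in wild type and by 3.75 in C406A. Its share thus depends on where values under the floor are set. The effect of the floor stays open for RNR3, whose difference was -1.65 with no floor (adjusted p = 0.636, limma) and which had no value at the higher floor of 148.4. The checkpoint list as a whole kept about the share of matched lists, so a loss of induction particular to that list was not seen. For RNR3 and HUG1 alone such a loss stays open.

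Untreated mutants were set against the MMS response of the other mutant, so that no array served both sides. Of 684 genes induced in C406A, 542 (79.2%) stood higher in untreated C403A than in wild type, and of 604 repressed genes 443 (73.3%) stood lower (r = 0.343 across genes). Of 452 genes induced in C403A, 305 (67.5%) stood higher in untreated C406A, and of 383 repressed genes 252 (65.8%) stood lower (r = 0.144). These genes are not independent of each other.

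The number of genes in the mean MMS response was tested with other splits of the 12 arrays into 6 and 6. Of 100 splits, 1 called as many genes, the real split, with 2409 in a model with genotype. The highest of the others called 1075 and differed from the real split in only 2 arrays. A random division of these arrays is thus argued against as the source of that number. The splits treat arrays as exchangeable, so chance differences between cultures cannot be excluded if arrays of a group share a culture.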
